A study of Drosophila melanogaster with 4 samples.

How the data were processed

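Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole wild-type Drosophila melanogaster embryos of the Oregon-R strain, at 14 to 16 h of development, with an antibody against POF, a protein named for painting the fourth chromosome. Per the labels' protocols, embryos were fixed in 1.8% formaldehyde and the antibody-bound chromatin was recovered on beads. The series holds 4 samples, of which 2 are ChIP replicates and 2 are the matching inputs, total chromatin DNA that was not immunoprecipitated. Groups and replicate numbers were taken from the sample titles, and each input is named in its label as the background of 1 ChIP replicate. Nothing in the labels says whether the replicates came from separate embryo collections, so the spread between them may be technical.

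The files used were 3 lists of regions that the authors had called as significantly enriched, with 1 list for each ChIP replicate and 1 list for the replicate set, called here the combined list. Coordinates are 1-based on FlyBase release 5, per the file headers, which also give the lengths of 14 sequences. Bowtie 0.12.7 is named in the submitters' processing notes, which do not say how it was run. The region caller, its threshold and the way the replicates were combined are not given in the sources used here. The lists differ in their minimum width, which was 1301 bp in both replicate lists and 1001 bp in the combined list, so the combined list was not a simple union of the other two. Read counts and depths were not part of the lists, so the depth behind each region is unknown, and the inputs were not analysed here on their own.

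Each region carries 1 deposited score, an enrichment value made by the authors whose scale the file headers do not state. The scale was tested from the values. Among regions away from the commonest score of their list, 23.8% of replicate 1 scores, 11.9% of replicate 2 scores and 13.3% of combined scores differed from that commonest score by the base-2 logarithm of a ratio of whole numbers up to 60, within 1e-09. With natural logarithms the matches were 0 in each list, and with base-10 logarithms they were 0, 1 and 2 regions. The scores were therefore read as base-2 logarithms of a ratio and were described, ranked, filtered and compared between chromosomes or groups of regions only within a list.

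Regions were compared by overlap of at least 1 bp. The chance level of overlap came from 10000 rotations of the replicate 2 regions around each chromosome, which keep widths and spacing, with a one-sided p. The number of regions on chromosome 4 was tested against its share of sequence length with an exact two-sided binomial test. Covered base pairs were tested with 10000 placements of the regions by chromosome length, two-sided. Median scores and widths were compared with two-sided permutation tests of 100000 resamples. These tests take regions as the unit. Regions are not replicates, so each p describes 1 list or pair of lists. Across the 2 replicates, an exact two-sided sign-flip permutation test of the log2 density and coverage ratios gave p = 0.5 for chromosome 4 and for X, the smallest that 2 replicates allow, so this design cannot pass the threshold. The 28 planned tests were adjusted together by the Benjamini-Hochberg method, and the p-values of alternatives and of tests in the closing observations are unadjusted. Shares of regions have 95% Wilson intervals, which cover counting error only. The sequence called Uextra, of 29.0 Mb, had 0 regions in every list and was left out of the lengths compared, which leaves 13 sequences of 139.7 Mb. Means over the replicates are given with their SD. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

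The tests were tried on simulated lists of 3139 regions on the same chromosome lengths. Within a list the simulated regions were placed independently at random, without clustering. The runs therefore cannot show how often the density test, which takes regions as independent, passes by error when regions are clustered. The rotation test passed the threshold of 0.05 in 0 of 10 runs with no shared regions and in 10 of 10 runs with 40 percent of regions shared. The density test passed in 1 of 20 runs with equal density and in 19 of 20 runs with a fold of 2 on chromosome 4. The permutation test of widths passed in 2 of 20 runs with equal widths and in 20 of 20 runs with widths multiplied by 1.3.

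The comparisons, the rule for naming regions and the main alternatives were fixed before the data were examined. The rule named the 10 regions on chromosome 4 and the 10 elsewhere with the best combined score among those that overlapped both replicate lists. Alternatives were a reciprocal overlap of 50%, regions extended by 500 bp, the better scoring 50% of each list, neighbours closer than 1000 bp merged, lists of equal length, the main chromosome arms only, covered base pairs, 50-kb bins and each replicate alone. Planned comparisons of genes, promoters and gene lists were not made. The gene table used here has Release 6 coordinates and the regions have release 5 coordinates, so regions are named by position and not by gene.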

Results

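POF is an RNA-binding protein known for coating chromosome 4, the smallest autosome of Drosophila melanogaster. The experiment mapped chromatin of late embryos recovered with an antibody against POF. The only controls were inputs, so nonspecific recovery cannot be told apart from POF binding at a given region. Replicate 1 had 3139 enriched regions that covered 5.99 Mb. Replicate 2 had 2853 regions that covered 5.44 Mb. The combined list had 11489 regions that covered 19.4 Mb, or 13.9% of the sequence considered. Median widths were 1807 bp in replicate 1, 1855 bp in replicate 2 and 1444 bp in the combined list. The median deposited scores were 0.700, 0.653 and 0.484, and they are not compared across lists. Regions lay on every main chromosome arm in every list. The heterochromatic and unplaced sequences held few of them, with 275 of the 11489 combined regions.

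The first comparison asked whether the 2 replicates marked the same places. Of the replicate 1 regions, 1737 overlapped a replicate 2 region, which is 55.3% (95% Wilson interval 53.6 to 57.1). Of the replicate 2 regions, 1742 overlapped a replicate 1 region, which is 61.1% (59.3 to 62.8). Random rotation gave 8.90% and 9.76%, and none of 10000 rotations reached the observed shares (permutation by rotation, p = 0.0001 for each, the smallest that these rotations can give, adjusted p = 0.0002). The bases shared by both lists made up 40.2% of their union, against 2.49% under rotation. On X, 56.4% of the replicate 1 regions were shared, and on 2L, 2R, 3L and 3R together 54.6% were. Chromosome 4 had 61 of 77 replicate 1 regions shared, or 79.2% (68.9 to 86.8), and 60 of 77 replicate 2 regions, or 77.9% (67.5 to 85.7). Rotation along chromosome 4 gave 23.6% for the replicate 1 share (permutation by rotation, p = 0.0023, adjusted p = 0.0038), and the replicate 2 share lay above the mean of its rotations (permutation by rotation, p = 0.0018, adjusted p = 0.0034), although some rotations reached the observed share in each. Small offsets, which nearly restore the true positions on so short a chromosome, were not left out of the rotations.

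Regions present in both replicates had the higher scores. In replicate 1 the median score was 0.726 for the 1737 shared regions and 0.682 for the 1402 others, a difference of 0.0439 (permutation p = 1e-05, the smallest that the resamples can give, adjusted p = 4.7e-05). In replicate 2 the medians were 0.681 for 1742 shared and 0.626 for 1111 other regions, a difference of 0.0543 (permutation p = 1e-05, adjusted p = 4.7e-05). The share of overlapping regions was 87.3% among the top 10% of replicate 1 scores and 93.4% among the top 10% of replicate 2 scores. It did not fall steadily towards low scores: the lowest 10% of scores still had 52.5% and 60.5%. Width was not held equal in these comparisons. Scores rose with width on X, 2L, 2R, 3L and 3R (Spearman rho 0.487 in replicate 1 and 0.538 in replicate 2). The higher scores of shared regions may therefore partly reflect width.

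Chromosome 4 was the most densely covered arm in each of the 3 lists. Regions covered 13.4% ± 0.371 of chromosome 4 (SD, n = 2 replicates), against 5.29% ± 0.471 of 2R, 4.85% ± 0.316 of X, 4.82% ± 0.218 of 3R, 4.38% ± 0.291 of 2L and 3.70% ± 0.396 of 3L. The gap between chromosome 4 and 2R, the next arm, was larger than the spread between the replicates. Both replicates had 77 regions on chromosome 4, or 57.0 per Mb, while the remaining 12 sequences had 22.1 per Mb in replicate 1 and 20.1 per Mb in replicate 2. The number of regions per Mb was thus 2.57 times that of the rest in replicate 1 (exact binomial p = 7.8e-13, adjusted p = 1.1e-11) and 2.84 times in replicate 2 (p = 6.4e-15, adjusted p = 1.8e-13). Covered sequence was 3.12 and 3.59 times that of the rest (permutation by random placement, p = 0.0001 for each, the smallest that 10000 placements can give, adjusted p = 0.0002). The rest includes unplaced sequence with few regions, such as U at 1.39 and 1.29 per Mb, which raises these ratios. Among the other main arms 2R was the densest, at 30.2 regions per Mb in replicate 1 and 26.5 in replicate 2.

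The combined list gave a different answer for the number of regions than for the sequence they covered. Chromosome 4 had 130 combined regions, or 96.2 per Mb, against 82.1 per Mb elsewhere, a ratio of 1.17 that did not pass the test (exact binomial p = 0.078, adjusted p = 0.11). 2R had more, at 110 per Mb. Those 130 regions covered 24.8% of chromosome 4, while 13.8% of the rest was covered, a ratio of 1.79 (permutation by random placement, p = 0.0001, adjusted p = 0.0002). Against the main arms only, the coverage ratio was 1.58 and the ratio of regions per Mb was 1.03 (exact binomial p = 0.69, unadjusted). Split after the data had been seen, the ratio was 3.08 among combined regions that overlapped both replicate lists and 0.718 among those that overlapped neither, a contrast that follows from the density of the replicate lists and is not separate evidence. In the better scoring 50% of the combined list the ratio was 0.844 (exact binomial p = 0.28).

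**Figure D1:**
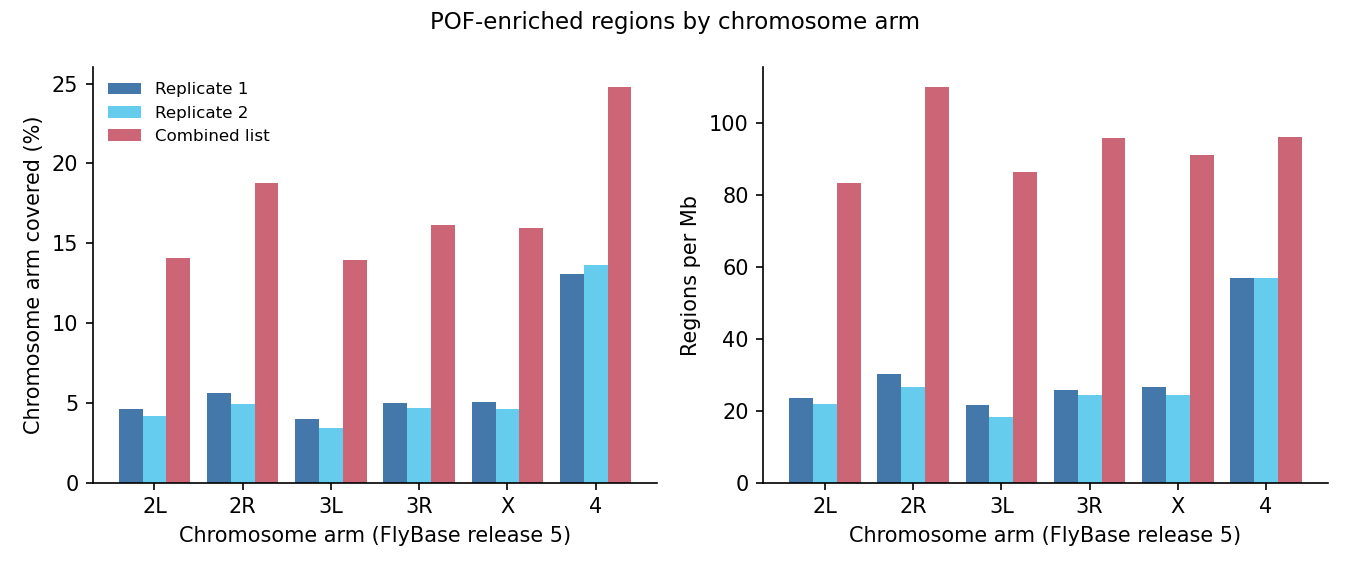
Percent of each chromosome arm covered by enriched regions (left) and number of regions per Mb (right), for replicate 1, replicate 2 and the combined list; each bar is 1 list. Chromosome 4 has the tallest bars in both replicates, at 13.1% and 13.6% covered and 57.0 regions per Mb, and in the combined list it leads in coverage at 24.8% but not in number.

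Along chromosome 4 the regions were spread over most of its 1.35 Mb. The bin from 1000001 to 1100000 was the most covered, with 26.2% in replicate 1, 21.8% in replicate 2 and 37.5% in the combined list. The bin from 700001 to 800000 was a trough, with 1.40%, 3.33% and 10.6%. The distal end from 1300001 to 1351857 had 0 regions in both replicate lists and 6.80% coverage in the combined list. Coverage of the 14 bins of 100 kb rose and fell together in the replicates, with a Pearson r of 0.904 (permutation p = 3e-05, adjusted p = 0.00012) and a Spearman rho of 0.741 (p = 0.0033, adjusted p = 0.0051). Without the 2 bins farthest from the median, the trough and the distal end, r was 0.787 and rho 0.587 over 12 bins. Neighbouring bins are not independent.

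**Figure D2:**
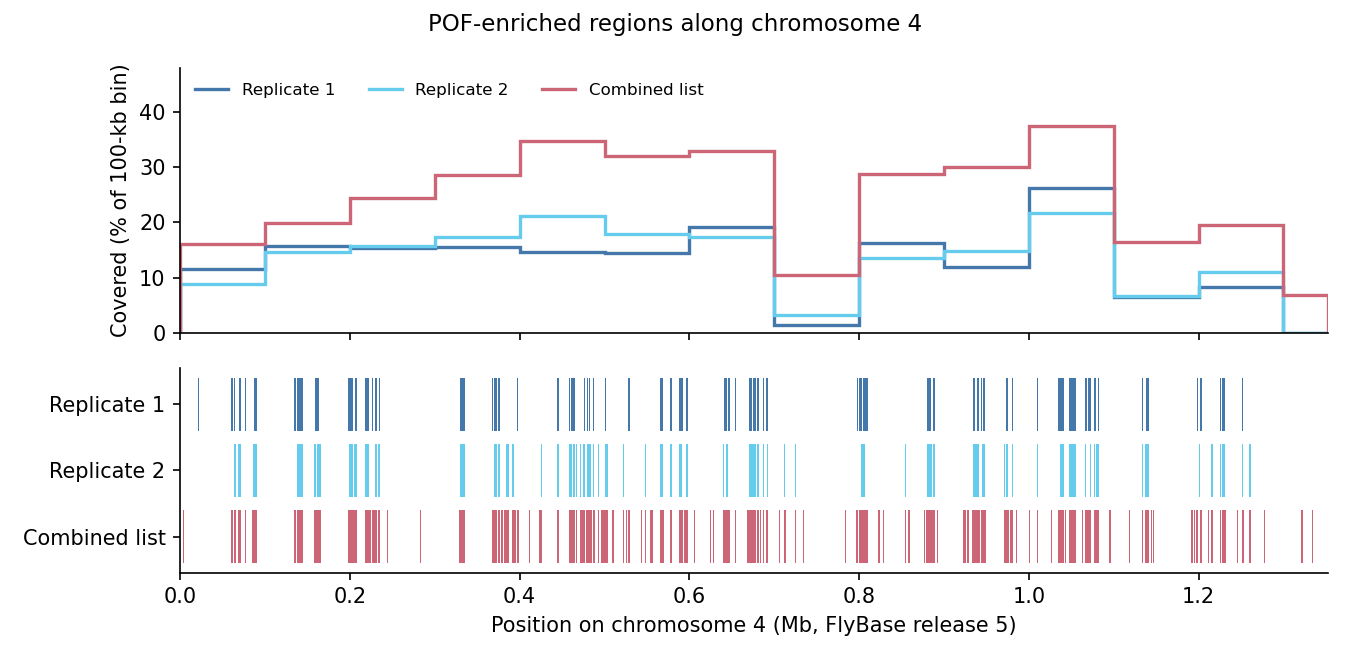
Chromosome 4 on FlyBase release 5, with position in Mb on the horizontal axis. The upper panel gives the percent of each 100-kb bin covered in each list, and the lower panel draws every enriched region to scale; the trough between 700001 and 800000 and the peak between 1000001 and 1100000 appear in all 3 lists.

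Regions on chromosome 4 scored lower than regions elsewhere and were wider in the combined list. The median score on chromosome 4 was 0.645 against 0.702 in replicate 1 (difference -0.0575, permutation p = 0.0056, adjusted p = 0.0082). In replicate 2 it was 0.592 against 0.656 (difference -0.0634, permutation p = 0.002, adjusted p = 0.0035). In the combined list it was 0.441 against 0.484 (difference -0.0427, permutation p = 1e-05, adjusted p = 4.7e-05). Elsewhere includes X, whose scores were higher, and against 2L, 2R, 3L and 3R alone the differences were smaller, at -0.0366, -0.0436 and -0.0310 (permutation p = 0.035, 0.017 and 0.00011, unadjusted, chosen after the data had been seen). The median width of combined regions was 1866 bp on chromosome 4 and 1440 bp elsewhere (permutation p = 1e-05, adjusted p = 4.7e-05). The width difference did not pass the test in replicate 1, with 1952 against 1803.5 bp (permutation p = 0.097, adjusted p = 0.13), or in replicate 2, with 1921 against 1850 bp (p = 0.42, adjusted p = 0.43). The better scoring 50% of the combined list, with 47 regions on chromosome 4, is selected by the score itself, so its score difference of 0.0363 does not bear on the direction in the whole list. The width difference, 426 bp in the whole combined list, was 2293 bp in that subset and 1263.5 bp among regions in both replicate lists, a split chosen after the data had been seen. Both subsets also select by width, so these larger differences are not stronger evidence. Combined scores rose with width on chromosome 4 (Spearman rho 0.490) but hardly on the other main arms (0.0597), and regions in both replicate lists were wider.

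**Figure D3:**
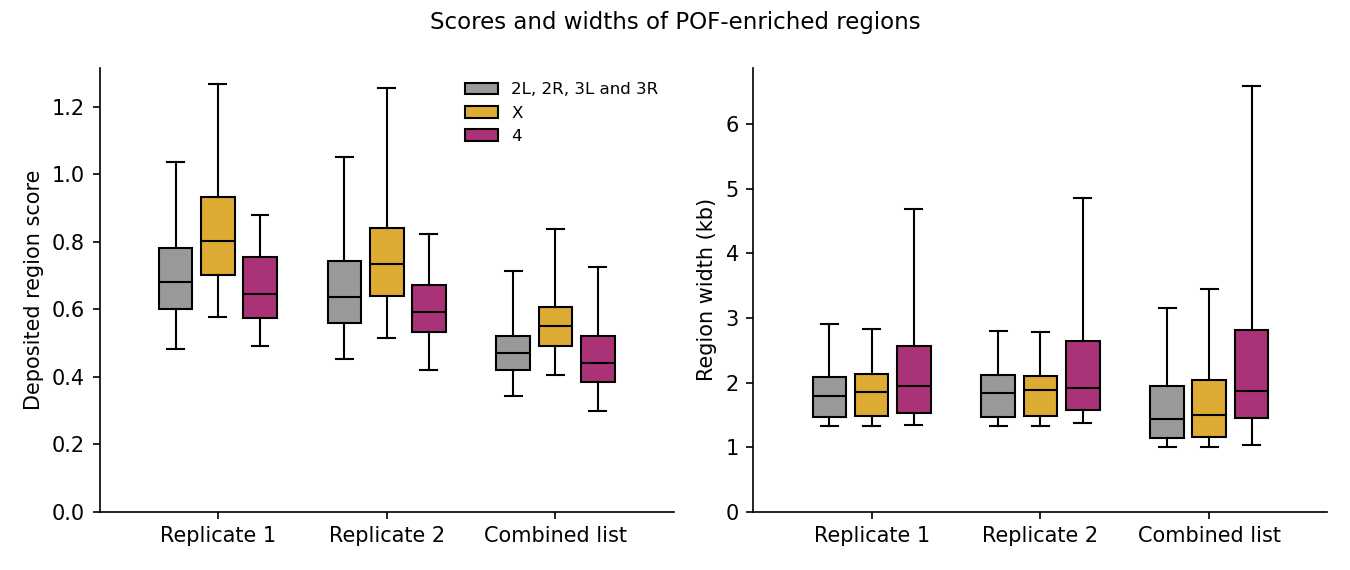
Deposited region scores (left) and region widths in kb (right) for the autosome arms 2L, 2R, 3L and 3R, for X and for chromosome 4, in each list; boxes span the 25th to 75th percentile with a line at the median, and whiskers the 5th to 95th percentile. Chromosome 4 has the lowest median score in each list, and its widths reach highest, with a 95th percentile of 6593 bp in the combined list.

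The strongest reproducible region of chromosome 4 ran from 885653 to 888861, with a combined score of 1.11, a score of 1.21 in replicate 1 and 1.39 in replicate 2. The region next to it, from 879304 to 885592, had the next best score at 0.826. It was followed by 369247 to 373898 at 0.793, 218141 to 223131 at 0.790 and 157530 to 165515, a region of 7986 bp, at 0.731. The remaining 5 of the 10 named regions on this chromosome scored between 0.678 and 0.719 and included the 9133 bp from 669896 to 679028 and the 9101 bp from 1046870 to 1055970. All 10 were matched by at least 1 region in each replicate list, as the naming rule required.

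Outside chromosome 4, the best scores were above those on it, whose strongest named region ranked 181 in the combined list. On X, the region from 14074394 to 14077956 had a combined score of 2.55, with 2.34 in replicate 1 and 2.75 in replicate 2, where it ranked 7 and 3 in its list. Another pair of X regions, from 2218611 to 2221292 and from 2631788 to 2634095, scored 1.99 and 1.69. On 2R, the region from 18791443 to 18801037 scored 2.07 in the combined list, and its replicate scores of 2.82 and 3.27 ranked 5 and 1. On 3R, 12976366 to 12978687 scored 1.98 and 18575329 to 18577694 scored 1.80. The other 4 named regions lay on 2L, 2R and 3L and scored between 1.59 and 1.79. Genes at these positions were not assigned, because no annotation on release 5 coordinates was used here. Whether these regions reflect POF binding or nonspecific recovery was not tested.

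X was compared with the large autosome arms, since POF has known binding sites on X as well. X had 26.6 regions per Mb in replicate 1 and 24.4 in replicate 2, against 25.1 and 22.7 on 2L, 2R, 3L and 3R together. The ratios of 1.06 and 1.08 did not pass the test (exact binomial p = 0.23 and 0.12, adjusted p = 0.25 and 0.15). In the combined list the ratio was 0.976 (exact binomial p = 0.33, adjusted p = 0.35). Covered sequence was 1.06, 1.08 and 1.02 times that of the autosome arms in replicate 1, replicate 2 and the combined list (permutation by random placement, p = 0.2, 0.13 and 0.51, adjusted p = 0.23, 0.16 and 0.51). In the better scoring 50% of the combined list X had 1.74 times as many regions per Mb, a subset that favours X because its median score was higher, at 0.550 against 0.472.

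The last comparison set the combined list beside the replicate lists. The combined list held 97.4% of the replicate 1 regions and 97.9% of the replicate 2 regions, including 76 of the 77 on chromosome 4 in each. Only 1711 combined regions, or 14.9% (95% Wilson interval 14.3 to 15.6), overlapped both replicate lists, while 7468, or 65.0% (64.1 to 65.9), overlapped neither. On chromosome 4, 50 of 130 regions, or 38.5% (30.5 to 47.0), overlapped both lists and 52, or 40.0%, overlapped neither. Regions in both lists were wider, with a median of 2500 bp against 1237.5 bp for regions in neither, and scored 0.615 against 0.477. On chromosome 4 these medians were 3756.5 bp against 1368 bp and 0.544 against 0.415. The combined list was made from the same samples, so these differences and its overlap with them were not tested. Over all chromosomes, the median width of regions in neither list lay below 1301 bp, the minimum width of both replicate lists. The unlike minimum widths may therefore account for part of these shares and width differences.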

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

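The tests that counted Uextra in the rest, compared chromosome 4 with the autosome arms alone, or kept only combined regions found in both or in neither replicate list, were chosen after the result was seen. Leaving out the 2 bins of chromosome 4 farthest from the median was also not planned, and the other alternatives were planned. The overlap of the replicates, the higher scores of shared regions and the agreement of the bins along chromosome 4 kept their direction and their side of the threshold under each alternative run for them. The combined density ratio of chromosome 4, 1.17, was 0.844 in the better scoring 50% of the list (exact binomial p = 0.28), 1.42 with Uextra in the rest, 1.79 for covered base pairs, 3.08 for regions in both replicate lists and 0.718 for regions in neither, and 2.57 to 2.84 in a single replicate list. The X ratio, 0.976, passed the threshold at 1.74 in the better scoring 50% (exact binomial p = 8.8e-72), 2.97 in the top 2853 regions (p = 6.7e-152) and 0.931 for regions in neither replicate list (p = 0.02). It did not pass at 1.02 for covered base pairs, 1.08 for regions in both replicate lists, and 1.06 to 1.08 in a single replicate list. The score difference of chromosome 4, -0.0427, was -0.0310 against the autosome arms alone and -0.0736 for regions in both replicate lists (permutation p = 0.016). It was -0.0575 and -0.0634 in the single replicate lists, and 0.0363 in the better scoring 50%, which is selected by the score itself. The width difference, 426 bp, was 2293 bp in the better scoring 50%, 1263.5 bp for regions in both replicate lists, and 71 to 148.5 bp in a single replicate list, no longer past the threshold. The share of combined regions in both and in neither replicate list was 12.7% and 66.9% with reciprocal overlap of 50%, 18.5% and 59.1% with 500 bp extensions, 12.6% and 69.4% in the better scoring 50%, and 17.2% and 62.2% after merging neighbours. For all of these the cause was not tested, except that ranking by score selects X regions, whose scores were higher, and that density in regions found in both or in neither replicate list follows from the density of those lists. The width differences of 2293 and 1263.5 bp may also reflect selection by width in their subsets, in the better scoring 50% mainly on chromosome 4. Why combined scores followed width more closely on chromosome 4 was not tested. The depth of the libraries is unknown, so regions absent from a list cannot be separated from regions too weak to be called.

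No paired analysis was possible because the inputs were not analysed here on their own and each ChIP list already stands for 1 ChIP and input pair. Alternatives for genes and gene lists were not run, as no release 5 annotation was used here. A correlation over bins has no value without a replicate, reciprocal overlap gives no shared base pairs, and the X comparison uses the main arms already.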

Other observations

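The comparisons of windows, of overlap on chromosome 4 and of X scores, the tests of few reads at high scores, of strong X sites and of averaging over width on and off chromosome 4, and the test of whether both replicates lie in the wide regions, were chosen after the result was seen.

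In windows of 100 kb, chromosome 4 stood among the most covered stretches of the genome in the replicate lists, and less so in the combined list. Of its 13 whole windows, 8 in replicate 1 and 9 in replicate 2 were among the top 60 of 1202 windows on the main arms, but 4 were in the combined list. Median coverage of a window was 14.6% on chromosome 4 and 4.10% elsewhere in replicate 1, and 14.8% and 3.61% in replicate 2. In the combined list it was 28.5% and 14.9%, and the 95th percentile of the windows elsewhere was 31.7%. Other arms held most of the top 60, with 52, 51 and 56 of them in replicate 1, replicate 2 and the combined list, and 37, 14 and 96 of the 1189 windows elsewhere lay above the median of chromosome 4. The window of 3R from 12000001 to 12100000 had 26.7% and 28.8% coverage in the replicates and 61.1% in the combined list, the highest of all windows by the lower of the replicate values. It holds the widest combined region, 12825 bp from 12070171 to 12082995. The 3L window from 600001 to 700000 had 22.1% and 18.9%, the 3R window from 1400001 to 1500000 had 19.8% and 18.1%, and the X window from 1900001 to 2000000 had 26.5% and 16.5%. The widest region of both replicate lists lay on 2L, from 12002156 to 12013453 in replicate 1 and from 12002216 to 12008612 in replicate 2.

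Regions on chromosome 4 were found again more often than regions elsewhere. The share overlapped by the other replicate was 79.2% against 54.7% for replicate 1 (Fisher's exact test, two-sided, p = 1.3e-05) and 77.9% against 60.6% for replicate 2 (p = 0.0019). Chance overlap is also higher on chromosome 4, since more of it is covered, and the difference beyond that chance was not tested.

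Scores on X were higher than on the autosome arms in each list, although the ratio of its density to theirs did not pass the test. The median was 0.802 on X and 0.681 on 2L, 2R, 3L and 3R in replicate 1, 0.735 and 0.636 in replicate 2, and 0.550 and 0.472 in the combined list (permutation p = 1e-05 for each, the smallest that the resamples can give). A few strong sites on X are argued against as the whole cause, because the 25th percentile was higher by 0.102 in replicate 1 (bootstrap interval 0.0878 to 0.117) and by 0.0803 in replicate 2 (lower bound 0.0633). Fewer reads over X, as a mixed population of males and females would give, may raise the ratio a region needs to be called. Whole-number matches were scores equal to the list's commonest score, or differing from it by log2 of a ratio of whole numbers up to 60. In replicate 1 they made up 30.9% on X against 22.9% on the autosome arms (Fisher's exact p = 8.1e-05). In replicate 2 they made up 16.1% against 11.6% (Fisher's exact p = 0.0061). X and the autosome arms were not compared at equal score. In the combined list such matches were 75.9% of regions scoring over 1.5 against 14.3% of all regions. The higher share on X may therefore follow from its higher scores, and cannot decide whether fewer reads lie over X. A broad difference in POF on X remains open and was not tested.

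The highest combined scores lay mostly in narrow regions that neither replicate list held. Of 79 combined regions scoring over 1.5, 59 overlapped neither list, with a median width of 1007 bp against the minimum of 1001, and 16 overlapped both, with a median width of 2603.5 bp. Ratios of few reads are a candidate explanation: 94.9% of the 59 scores were whole-number matches, as defined for X, against 0% of the 16 (Fisher's exact p = 1.1e-13). The groups were not matched for width: 49 of the 59 were at most 1100 bp wide, against 0 of the 16. The contrast may therefore follow from width, and a match can also arise from many reads. It cannot decide whether few reads made these scores high. Repeat-rich sequence may also contribute, since 55.9% of the 59 lay on heterochromatic or unplaced sequence (Wilson interval 43.3 to 67.8) against 2.39% of all combined regions. The interval does not decide whether it accounts for most of them. No biological explanation was tested, and the best scoring region found in both replicate lists ranked 22 in the combined list.

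Chromosome 4 had a tail of wide regions, with 14 of its 130 combined regions, or 10.8%, at least 5000 bp wide, against 0.599% elsewhere (Fisher's exact p = 3.2e-13). The median score of these 14 was 0.611, against 0.648 for regions as wide elsewhere, and that of the narrower regions was 0.423 on chromosome 4 and 0.483 elsewhere, differences that were not tested by width. Scores did not fall with width. On chromosome 4 they rose with it, with a Spearman rho of 0.643 in replicate 1 (bootstrap interval 0.462 to 0.778), 0.740 in replicate 2 (0.618 to 0.823) and 0.490 in the combined list (0.314 to 0.632). Off it rho was 0.487 (0.456 to 0.515), 0.538 (0.508 to 0.567) and, close to flat in the combined list, 0.0597 (0.0389 to 0.0796). These correlations cannot decide whether averaging over width lowers scores, because width and score may both follow the strength of enrichment. That the wide combined regions come from 1 replicate alone is argued against, because all 14, or 100%, overlapped both replicate lists (Wilson interval 78.5 to 100), with at least 47.6% of the length of each covered in replicate 1 and 38.5% in replicate 2. Most were not 1 region in the replicates. Among the named ones, 669896 to 679028 overlapped 2 replicate 1 and 3 replicate 2 regions, and 1046870 to 1055970 overlapped 2 and 2. The counts were 1 and 2 for 157530 to 165515, and 2 and 1 for 328536 to 335603. Among all 14, only 879304 to 885592 and 1136431 to 1142027 overlapped just 1 region of each replicate. Every other one overlapped more than 1 region in at least 1 replicate. Joining of close neighbours was not tested. Whether regions called this wide in a replicate list itself are more frequent on chromosome 4 in both replicates stays open, as they were 2.60% of chromosome 4 regions against 0.425% in replicate 1 (Fisher's exact p = 0.051) and 3.90% against 0.252% in replicate 2 (p = 0.002), from 2 and 3 regions, and no biological explanation was tested.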
